A study of Arabidopsis thaliana with 12 samples.

How the data were processed

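Small RNA (RNA under 200 nt) from the aerial tissue of 18-day-old Arabidopsis thaliana plants was sequenced in 12 libraries. There were 4 genotypes with 3 libraries each: wild-type Col-0, the double mutant ein5-1 ski2-3, the single mutant rdr6-11 and the triple mutant rdr6-11 ein5-1 ski2-3. EIN5 (also called XRN4) is the cytoplasmic exonuclease that degrades uncapped RNA from its 5' end. SKI2 is the RNA helicase that helps the cytoplasmic exosome degrade RNA from its 3' end. RDR6 is an RNA-dependent RNA polymerase that turns single-stranded RNA into the double-stranded precursors of secondary siRNAs.

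The deposited table holds whole-number read counts per gene model, with 1 column for each of the 12 libraries. Per the file headers it also holds 3 further kinds of value computed by the authors. The signal values in the deposited table are group means of counts divided by DESeq size factors. The authors' fold changes are ratios of those means for ein5-1 ski2-3 over Col-0 and over the triple mutant. The authors' p-values, plain and adjusted, belong to the same 2 comparisons. The submitters' processing notes name CASAVA 1.8.2, Bowtie, Bowtie2, DESeq and the TAIR10 build without roles or settings. The table gives neither read length nor strand, so siRNAs, miRNAs and fragments of longer RNAs were counted together in each gene, and a gene's value is the sum of all small RNA assigned to it. How reads with several matches were assigned is not stated.

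Gene names, classes, exons and positions came from the TAIR10 reference annotation. Of 30926 genes in the table, 30403 matched a locus there, and 29938 had at least 1 count. At least 100 counts and a count profile identical to that of another gene were found for 445 genes, among them 326 of the 557 tRNA genes with that many counts. Values of near-identical copies therefore do not say which copy the reads came from.

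Total counts per library lay between 2358724 and 2909767. The median gene had 1 to 3 counts per library, so small changes in weakly covered genes were not detectable at this depth. Intervals and floors given with counts cover counting error only, because the reads carry no molecular identifiers.

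Before the tests, the libraries of each group were compared pair by pair with a chi-square per gene. Replicates 1 and 2 of ein5-1 ski2-3 agree within sampling noise, with a mean chi-square of 1.00 per gene over 3762 protein-coding genes. Replicates 2 and 3 of Col-0 had 1.02 over protein-coding genes but 1.60 over all genes with distinct profiles, and were kept apart. Over all those genes the mean for ein5-1 ski2-3 replicates 1 and 2 was 1.05, a small excess over pure counting noise that the chi-square over so many genes detects. Those 2 ein5-1 ski2-3 libraries were therefore summed and treated as 1 sample. The plan written beforehand had a fit to all 12 libraries, so this sum departs from it. The model had 11 samples: 3 for Col-0, 2 for ein5-1 ski2-3, 3 for rdr6-11 and 3 for the triple mutant. Replicate numbers did not pair libraries across genotypes: none of 18 pairs with the same number had a residual correlation above 0.1, and the range was -0.113 to 0.047.

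Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 7219 genes. The filter asks for enough counts in as many samples as the smallest group has, 2 in ein5-1 ski2-3. A gene near 0 elsewhere can therefore enter through that group alone, which favours genes higher there, also among list members. Libraries were scaled by TMM, and group means were compared with 2-sided quasi-likelihood F tests. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the number that also changed at least 2-fold was given beside it. The p-values measure the spread between samples, which may be technical as well as biological. The fitted contrasts were ein5-1 ski2-3 against Col-0, rdr6-11 against Col-0, the triple mutant against each of the other genotypes, and the interaction, which is the change from losing RDR6 in ein5-1 ski2-3 minus the change from losing it in wild type. Levels are given as TMM-normalised read counts (CPM), with the SD over samples. A group with 0 counts in all its libraries was set to a floor of 3 counts over the group, and the fold is then a lower bound. With 1 to 3 counts in a group, the ratio is given with its 95% counting interval.

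The genotype contrasts, thresholds, gene lists and the rule for named genes were chosen before the data were examined. The lists were TAS loci, known phased siRNA coding loci, miRNA target genes, nitrate reductase and SMXL genes, photosynthesis genes, cytosolic ribosomal protein genes, small RNA pathway genes, mRNA decay genes, ethylene signalling genes, floral organ genes and root genes. MIR genes and transposon genes were taken by annotation. Transposon genes were those whose product or note names a transposon, 85 in the table. Other loci annotated as plain pseudogenes, 3839 in all, are called untranscribed pseudogenes. Transposon-derived loci without such a note would fall in that class, and the transposon list would miss them. The nitrate reductase and SMXL list was picked from what is known of siRNAs in these mutants, so its counts are not independent evidence. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, in each contrast except the triple mutant against Col-0. They were tested again with an estimated correlation and with fry. Camera compares a list with the other tested genes, so its direction can differ from the sign of the list's median.

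Named genes followed this rule: the mutated genes and every tested TAS locus, then the 8 largest rises and the 5 largest falls among called genes whose libraries separated completely with a mean of at least 10 counts. The 4 called genes with the highest level in each direction and up to 4 called members of each list were added, as were up to 2 members that were not called. The text prints a part of the genes that the rule takes. Genes taken outside the rule are said to be so. A gene was put in the RDR6-dependent set if it was called at least 2-fold higher in ein5-1 ski2-3 than in Col-0 and at least 2-fold lower in the triple mutant than in ein5-1 ski2-3. Both contrasts use the ein5-1 ski2-3 libraries, so the overlap with no change in any group was simulated.

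The alternatives were RLE size factors, scaling to total counts, scaling to the summed counts of MIR genes, the Wald test of DESeq2 1.42.0, no filter, a filter of at least 10 counts in at least 3 libraries, a 2-fold minimum, only the libraries of the groups compared, the replicate number as a block, and leaving out each library. The fit to the 12 libraries counted apart was the one first planned. It became an alternative once ein5-1 ski2-3 replicates 1 and 2 were summed. These were added after seeing the data: the block with the libraries apart, a fit without rRNA, tRNA and organelle genes, and the RDR6-dependent set from only the groups compared. Scaling to MIR genes holds their summed counts level, so a MIR median in that scaling is drawn towards 0 by construction. The shares of counts by gene class were compared by exact permutation tests, 2-sided, which cannot go below p = 0.1 with 3 libraries against 3. The tests were checked on simulated data at the size of this design. There, 60% of genes changed 2-fold and 100% of genes changed 4-fold upward were called, against 42% and 70% downward. Of 7019 unchanged genes, 6 were called, and a simulated comparison without change called 0. A simulated list of raised genes was called by camera and one of unchanged genes was not. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for tables and exact tests.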

Results

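Small RNA reads per gene were counted in the aerial tissue of 18-day-old Arabidopsis plants of 4 genotypes, with 3 libraries each. The genotypes were Col-0, ein5-1 ski2-3 (the double mutant, which lacks both cytoplasmic RNA decay routes), rdr6-11 (which lacks the polymerase RDR6) and rdr6-11 ein5-1 ski2-3 (the triple mutant). Total counts of replicates 1 to 3 were 2750605, 2358724 and 2733682 in Col-0, and 2521831, 2575485 and 2909767 in ein5-1 ski2-3. They were 2632435, 2834954 and 2579417 in rdr6-11, and 2609941, 2717600 and 2701855 in the triple mutant. The mutated genes EIN5, SKI2 and RDR6 had at most 7 counts in any library and were not tested. Levels below are TMM-normalised CPM with the SD over samples, and n is 3 except in ein5-1 ski2-3, where replicates 1 and 2 formed 1 sample and n is 2.

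Most counts came from nuclear rRNA genes, which held 50.8% to 56.6% of each library. Chloroplast genes held 17.6% to 22.3% and nuclear tRNA genes 8.03% to 9.83%. Protein-coding genes held 6.34% to 6.45% in Col-0 and 10.7% to 11.7% in ein5-1 ski2-3. The same class held 6.64% to 6.69% in rdr6-11 and 7.41% to 7.50% in the triple mutant. TAS loci, the non-coding sources of trans-acting siRNAs, held 0.355% to 0.375% in Col-0 and 0.495% to 0.735% in ein5-1 ski2-3. Their share was 0.0051% to 0.0055% in rdr6-11 and 0.0108% to 0.0118% in the triple mutant. MIR genes, the miRNA precursors, held 2.29% to 2.45% in Col-0 and 5.29% to 6.09% in rdr6-11. They held 3.69%, 3.67% and 2.43% in replicates 1 to 3 of ein5-1 ski2-3, and 1.92% to 2.18% in the triple mutant. Among 65 comparisons of class shares by exact permutation, the smallest adjusted p was 0.105, because 3 libraries against 3 cannot go below p = 0.1.

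The first comparison, ein5-1 ski2-3 against Col-0, asked what losing both cytoplasmic decay routes does to small RNA. Small RNA appeared on many protein-coding genes that had almost none in wild type. SMXL5 (AT5G57130, chromosome 5, 23144947 to 23149615), a repressor-type protein related to strigolactone signalling, rose from 1.06 ± 1.01 CPM (SD, n = 3) to 868 ± 135 CPM (SD, n = 2). Its log2 change was 9.69 (adjusted p = 1.17e-39). NIA1 (AT1G77760, chromosome 1, 29235721 to 29239484) and NIA2 (AT1G37130, chromosome 1, 14158452 to 14161938) encode the nitrate reductases of nitrogen assimilation. NIA1 rose from 2.03 ± 1.47 to 105 ± 18.8 CPM and NIA2 from 21.2 ± 1.23 to 231 ± 30.1 CPM. In all, 2204 genes were higher and 1356 lower in the double mutant, of which 1526 and 629 changed at least 2-fold. Protein-coding genes made up 1318 of the higher and 640 of the lower genes. That split was 2492 to 54 scaled to total counts, 1775 to 175 scaled to MIR genes, 915 to 863 without rRNA, tRNA and organelle genes, and 1102 to 1007 without ein5-1 ski2-3 replicate 3.

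GRF5 (AT3G13960), a growth-regulating factor gene of leaf cell division, had 0 counts in Col-0 and 134 ± 26.1 CPM in ein5-1 ski2-3, at least 278-fold more. CRF2, a cytokinin response factor, stood at a ratio of 662 to Col-0, with a counting interval of 255 to 3615 because Col-0 gave 3 counts. The SR-repeat gene AT2G46630 was at least 52.2-fold higher. Of the nitrate reductase and SMXL genes, 8 of 8 tested were higher (8 when adjusted over the list alone), with a median log2 change of 4.93, or 3.97 with 1 gene set at its bound. The list passed camera (adjusted p = 1.29e-24) and kept its call with an estimated correlation (adjusted p = 0.00862). The list was chosen from published work on related samples, so its count is not independent evidence of its direction. SMXL4 (AT4G29920) had a ratio of 234 with a counting interval of 88.9 to 1264, NIA1 a log2 change of 5.69 and NIA2 one of 3.45. The authors' deposited table gives folds over Col-0 of 52.44 for NIA1, 10.88 for NIA2, 250.7 for SMXL4 and 814.9 for SMXL5.

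Of 77 miRNA target genes counted, 27 passed the filter and could be tested. Of these, 24 were higher and 0 lower (25 and 1 when adjusted over the list alone), with a median log2 change of 2.98. A gene near 0 elsewhere can pass the filter through ein5-1 ski2-3 alone. The counts, the median and the camera result therefore partly reflect which members could enter. Camera gave an adjusted p of 3.33e-16, and the call was lost with an estimated correlation (adjusted p = 0.058 with an estimated correlation). ARF6, an auxin response factor and target of miR167, rose by 6.70. The HD-ZIP III genes of leaf polarity and vasculature, targets of miR166, rose too. PHB rose by 5.49, REV by 5.21, and ATHB8 stood at a ratio of 137 with a counting interval of 43.5 to 1308. Of the genes known to give phased siRNAs in wild type, 19 of 24 were higher and 0 lower (the same counts adjusted over the list alone), with a median of 1.14 (camera adjusted p = 5.88e-11, and adjusted p = 0.163 with an estimated correlation). Among them, MYB75, an activator of anthocyanin synthesis, rose by 4.40. AFB2, an auxin receptor, rose by 2.62, the NB-LRR resistance gene AT5G43740 by 2.17 and the PPR gene AT1G62590 by 1.18.

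The TAS loci did not move together: 2 were higher and 4 lower of 8 tested (the same adjusted over the list alone), and camera gave an adjusted p of 0.738. Their median was -0.12, while their mean was 0.30 and the test pointed upward, and the median became 0.71 with libraries scaled to total counts and 0.34 scaled to MIR genes. TAS4 (AT3G25795), source of siRNAs against MYB genes, rose from 35.5 ± 9.08 to 359 ± 63.5 CPM, a log2 change of 3.33. TAS3A fell by 0.76 and TAS3B by 0.60, but scaled to total counts they stood at 0.07 and 0.23. TAS1A and TAS1C fell by 0.27 and 0.30, and turned to 0.56 and 0.53 scaled to total counts, and to 0.20 and 0.16 scaled to MIR genes. The value of TAS1A was not called without Col-0 replicate 1 (adjusted p = 0.0647). TAS3C rose by 0.80 from 28 counts in Col-0, a call that was lost without Col-0 replicate 1 (adjusted p = 0.115) or 3 (0.0897), without ein5-1 ski2-3 replicate 1 (0.0845), 1 and 2 (0.417) or 3 (0.142), and without rdr6-11 replicate 2 (0.105). TAS1B at 0.20 and TAS2 at 0.02 were not called, and both were lower without ein5-1 ski2-3 replicates 1 and 2, at -0.26 (adjusted p = 0.0409) and -0.41 (adjusted p = 2.32e-05). TAS2 also stood at -0.03 without ein5-1 ski2-3 replicate 3 and at -0.17 without rdr6-11 replicate 2.

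**Figure D1:**
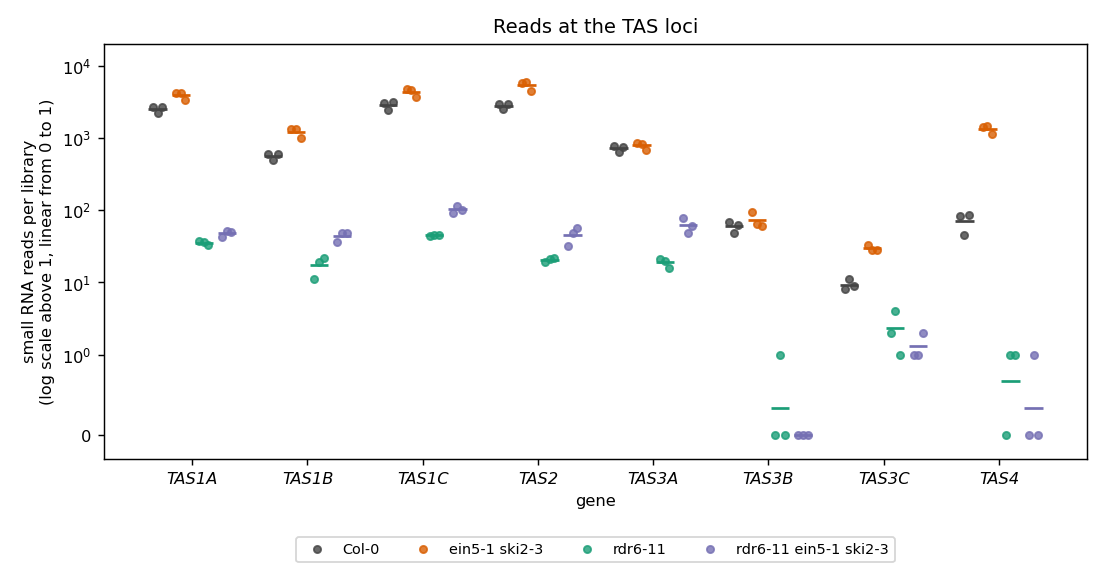
Reads per library (raw counts, symmetric log axis, linear from 0 to 1 and logarithmic above) at 8 TAS loci in 4 genotypes, with points for libraries and bars for group means. At TAS4 the Col-0 libraries hold 45 to 87 reads, those of ein5-1 ski2-3 hold 1151 to 1452, and those without RDR6 hold 0 or 1.

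In the main scaling, small RNA of the photosynthetic and translation machinery was lower in ein5-1 ski2-3. Of 20 photosynthesis genes, 15 were lower and 2 higher (16 and 2 adjusted over the list alone), and their median of -0.76 moved to 0.06 with libraries scaled to total counts. Camera gave an adjusted p of 3.99e-07, and adjusted p = 0.101 with an estimated correlation. RBCS1A, a gene for the small subunit of Rubisco with near-identical copies, so that the origin of its reads is uncertain, fell by 1.07. Of 22 cytosolic ribosomal protein genes, 7 were lower and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.58 that moved to 0.25 scaled to total counts. The call (camera adjusted p = 0.0121) was lost with an estimated correlation (adjusted p = 0.163 with an estimated correlation) and without ein5-1 ski2-3 replicates 1 and 2 (adjusted p = 0.0853). RPL4A fell by 0.99. The 18S rRNA gene AT3G41768, which has a near-identical copy, fell by 1.04. All 4 nuclear rRNA genes were lower, with a median of -0.74. Scaled to total counts, 2 were higher and 2 lower, with a median of 0.07. Of 568 tRNA genes, 468 were lower and 0 higher, a split that was 103 to 45 scaled to total counts. Large falls were those of FBA5, an aldolase gene that overlaps AT4G26520, at -2.60, the wax synthesis gene CER1 at -2.28, the defensin PDF1.2c at -2.15 and the histone gene HTA10 at -2.14.

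MIR genes went both ways, with 25 higher and 49 lower of 108 (26 and 50 adjusted over the list alone). Their median was -0.32, but 0.51 scaled to total counts and 0.12 scaled to MIR genes, and camera gave an adjusted p of 0.00245 (adjusted p = 0.587 with an estimated correlation). MIR845a rose by 5.54, the copper-responsive MIR408 by 1.88 and MIR398c, whose reads can also come from MIR398b, by 0.97, while MIR169f fell by 1.37. In the ethylene list, 2 of 5 genes were higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.282): EBF1, which targets ethylene transcription factors for degradation, rose by 1.96, and the transcription factor gene EIL1 by 1.37. None of the 3 tested mRNA decay genes was called (camera adjusted p = 0.899), and their median of 0.08 and mean of 0.18 were positive while the test pointed downward. Transposon genes had 8 higher and 3 lower of 15 (8 and 4 adjusted over the list alone, camera adjusted p = 0.731). Sadhu4-2 rose by 2.74 and the retrotransposon gene AT3G44570 fell by 0.47, which became 0.36 scaled to total counts. ADC1, which rose by 1.78, encodes arginine decarboxylase and counts as a transposon gene only through its annotation note. The root and floral organ lists and the small RNA pathway list had 2, 0 and 0 tested members and were not tested as lists. Both root genes rose: SHR stood at a ratio of 16.8 with a counting interval of 5.01 to 159, and SCR rose by 2.48.

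Of the 7219 genes, 64.5% had all samples of one genotype above all of the other, against 20% by chance for 2 samples and 3. The balance of calls depended on scaling: 61.9% of called genes were higher in ein5-1 ski2-3, against 53.2% with RLE size factors, 95.1% with total counts and 85.6% with libraries scaled to MIR genes. The median change of all genes was 0.29 in the main scaling, and 0.15, 1.11 and 0.72 in those alternatives. It was 0.05 without ein5-1 ski2-3 replicates 1 and 2, 0.04 without replicate 3, and 0.09 without rdr6-11 replicate 2 or with only the libraries of the groups compared. Without ein5-1 ski2-3 replicates 1 and 2 there were 1220 higher and 1329 lower genes, and without replicate 3 there were 1650 and 1839. The authors' deposited table calls 1333 genes higher and 976 lower in this comparison, and 1239 and 960 of them were called the same way here.

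**Figure D2:**
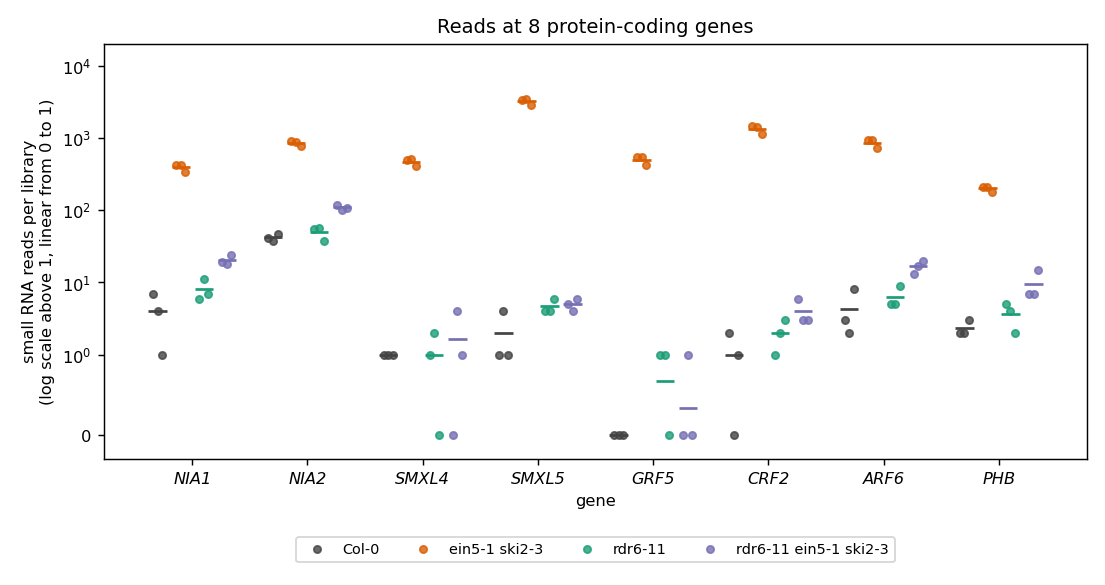
Reads per library (raw counts, symmetric log axis, linear from 0 to 1 and logarithmic above) at 8 protein-coding genes in 4 genotypes, with points for libraries and bars for group means. At SMXL5 the ein5-1 ski2-3 libraries hold 2833 to 3454 reads, while every other library holds at most 6.

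The comparison of rdr6-11 with Col-0 asked what losing RDR6 does while decay is intact. Small RNA of all 8 TAS loci collapsed, and so did that of most genes known to give phased siRNAs. TAS2 fell from 1407 ± 20.5 CPM (SD, n = 3) to 7.35 ± 0.595 CPM (SD, n = 3), a log2 change of -7.57 (adjusted p = 1.41e-42). TAS1A fell from 1261 ± 34.3 to 12.7 ± 0.930 CPM and TAS3A, source of the siRNAs against auxin response factors, from 361 ± 14.7 to 6.75 ± 0.885 CPM. AT1G63150 (chromosome 1, 23419294 to 23421714), one of the RNA-processing PPR genes, fell from 227 ± 8.81 to 1.06 ± 0.321 CPM. In all, 1541 genes were higher and 1104 lower, of which 776 and 238 changed at least 2-fold. Among protein-coding genes, 188 were higher and 497 lower, but 492 and 80 with libraries scaled to total counts, and 10 and 1943 scaled to MIR genes.

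The TAS list had 8 of 8 members lower (8 adjusted over the list alone), a median of -6.56 and a camera adjusted p of 2.90e-106, which held with an estimated correlation (adjusted p = 0.000111). The log2 change was -6.49 for TAS1C, -5.51 for TAS1B and -2.45 for TAS3C. TAS3B kept 1 count in rdr6-11, a drop with a counting interval of 45.5- to 10190-fold, and TAS4 kept 2 counts, with an interval of 41.5- to 1261-fold. Of the phased loci, 20 of 24 were lower (21 adjusted over the list alone) and 0 higher, with a median of -5.33 (camera adjusted p = 2.64e-104, and adjusted p = 0.00114 with an estimated correlation). The PPR genes AT1G63070, AT1G63080 and RPF3, which acts on mitochondrial transcripts, fell, with log2 changes of -7.47, -7.38 and -7.05.

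The miRNA target list did not pass camera (adjusted p = 0.317): 1 gene was higher and 2 lower of 27 (0 and 1 adjusted over the list alone), and the median was -0.23, or 0.22 scaled to total counts. SPL2, a flowering-time transcription factor gene and target of miR156, fell from 47.9 ± 0.252 to 1.18 ± 0.393 CPM, a log2 change of -5.29. TCP3, a leaf shape gene, fell by 1.22, a call lost without Col-0 replicate 2 (adjusted p = 0.0572) or 3 (0.0556) and without rdr6-11 replicate 2 (0.0984) or 3 (0.0682). The sulfate transporter gene SULTR2;1 rose by 1.91 from 3 counts, at a ratio of 3.77 with a counting interval of 1.16 to 21.3. That call was lost without Col-0 replicate 1 (adjusted p = 0.21) or 2 (0.0850) and without rdr6-11 replicate 1 (0.0808) or 2 (0.0965). Of the nitrate reductase and SMXL genes, 0 of 8 were higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.802), with a median of -0.17 that was 0.30 scaled to total counts. SMXL7 fell by 1.82, a call lost without Col-0 replicate 2 (adjusted p = 0.0923) and without rdr6-11 replicate 2 (0.0693). NIA2 was not called at -0.26.

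MIR genes were higher as a group in rdr6-11, with 86 of 108 higher and 0 lower (93 and 0 adjusted over the list alone). The median was 0.76, and 0 with libraries scaled to MIR genes, a scaling that holds their summed counts level and so draws this median towards 0. Camera gave an adjusted p of 8.18e-25, and adjusted p = 0.0691 with an estimated correlation. MIR393b, whose miRNA targets auxin receptors, rose from 65.4 ± 3.98 to 181 ± 9.69 CPM. MIR166a and MIR159b, each with near-identical relatives, rose by 0.95 and 0.61, and stood at 0.18 and -0.17 scaled to MIR genes. Untranscribed pseudogenes rose alongside: 1209 of 1852 were higher and 9 lower with a median of 0.92, against 30 and 21 with a median of 0.16 scaled to MIR genes. This class can include transposon-derived loci whose annotation does not name a transposon. PSEUDOSRKA, a broken copy of a self-incompatibility receptor gene, was at least 20.7-fold higher than its 0 counts in Col-0. PAI1 and PAI2, near-identical genes of tryptophan synthesis that siRNAs silence in other accessions, rose by 3.25 and 2.48.

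Photosynthesis genes were lower, 18 of 20 and 0 higher (the same adjusted over the list alone), with a median of -0.62, or -0.15 scaled to total counts. Camera gave an adjusted p of 6.96e-08, and adjusted p = 0.0574 with an estimated correlation. RCA, the Rubisco activase gene, fell by 0.67 and RBCS3B by 0.62, and scaled to total counts they stood at -0.20 and -0.15 without a call. The 18S rRNA gene AT3G41768 fell by 0.64. The 4 nuclear rRNA genes had a median of -0.41, all lower, but 0.06 with 2 higher and 2 lower scaled to total counts. Ribosomal protein genes had 4 of 22 lower and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 0.156), with RPL3A down by 0.74, and their median of -0.36 was 0.10 scaled to total counts. No gene of the ethylene list (5 tested) or of the decay list (3 tested) was called (adjusted p = 0.802 each by camera), and EBF1 stood at -0.29. Transposon genes had 7 of 15 higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.273). AT3G44570 rose by 0.40, which became -0.37 scaled to MIR genes.

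Samples separated completely at 46.8% of genes, against 10% by chance. Of the called genes, 58.3% were higher, and 57.5%, 84.6% and 1.8% with RLE size factors, total counts and MIR scaling. Medians of all genes were -0.01 in the main scaling and -0.03, 0.45 and -0.77 in those alternatives.

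The comparison of the triple mutant with ein5-1 ski2-3 asked how much of the small RNA that accumulates without decay needs RDR6. The small RNA of SMXL5, SMXL4, NIA1, NIA2 and GRF5 that marked the double mutant was largely gone. SMXL5 fell from 868 ± 135 CPM (SD, n = 2) to 1.90 ± 0.391 CPM (SD, n = 3), a log2 change of -8.81 (adjusted p = 1.49e-40). NIA1 fell from 105 ± 18.8 to 7.70 ± 1.24 CPM and NIA2 from 231 ± 30.1 to 41.5 ± 4.45 CPM. GRF5 kept 1 count, and its drop had a counting interval of 199- to 43880-fold. In all, 1946 genes were lower and 1037 higher, of which 1157 and 257 changed at least 2-fold. Protein-coding genes made up 1075 of the lower and 620 of the higher genes, against 1683 and 148 scaled to total counts. Without ein5-1 ski2-3 replicate 3 the balance turned, with 752 lower and 991 higher, as it did without rdr6-11 replicate 2, with 861 and 923.

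Each of the 8 tested nitrate reductase and SMXL genes was lower (8 adjusted over the list alone), with a median of -3.24 (camera adjusted p = 6.57e-31, and adjusted p = 0.00167 with an estimated correlation). SMXL4 fell by 7.57. All 8 TAS loci were lower (8 adjusted over the list alone), with a median of -5.38, or -5.33 with TAS3B at its bound, and camera gave an adjusted p of 1.55e-77 (adjusted p = 0.000878 with an estimated correlation). TAS4 kept 1 count, and its drop had a counting interval of 530- to 116700-fold. TAS3B was at least 53.8-fold lower. The log2 change was -6.37 for TAS2, -5.85 for TAS1A, -4.91 for TAS1C, -4.28 for TAS1B, -3.92 for TAS3C and -3.17 for TAS3A. Phased loci were lower at 24 of 24 (24 adjusted over the list alone), with a median of -5.64, a camera adjusted p of 2.62e-142 and adjusted p = 0.000954 with an estimated correlation. AT1G63080 and RPF3 fell, with log2 changes of -9.02 and -8.28. The PPR genes AT1G63630 and RPF1 were at least 183-fold and at least 96.5-fold lower.

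Of the miRNA targets, 23 of 27 were lower and 0 higher (the same adjusted over the list alone), with a median of -2.04 (camera adjusted p = 4.78e-19, and adjusted p = 0.0163 with an estimated correlation). ARF6 fell by 5.18, SPL2 by 4.96, ATHB8 by 4.57 and PHB by 3.89. MIR genes had 8 higher and 36 lower of 108 (the same adjusted over the list alone, camera adjusted p = 0.325), with a median of -0.10 that was 0.02 with RLE size factors and 0.08 scaled to MIR genes. MIR408 fell by 2.23, and MIR156c, whose miRNA targets SPL genes, by 1.32. Among transposon genes 7 of 15 were lower and 0 higher (the same adjusted over the list alone), with a median of -0.80 that was -0.35 without ein5-1 ski2-3 replicate 3 (camera adjusted p = 0.00081, and adjusted p = 0.0509 with an estimated correlation). The call rested on 3 loci, and without them the other 12 had a median of -0.48 and a camera adjusted p of 0.854. These loci, AT3G44570, AT2G14000 and AT3G30820, which encode a retrotransposon ORF-1 protein, fell by 7.37, 4.78 and 4.18.

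Photosynthesis and ribosomal protein genes were higher in the triple mutant than in the double mutant. Of the former, 16 of 20 were higher and 0 lower (17 and 0 adjusted over the list alone), with a median of 0.60, or 0.16 scaled to total counts (camera adjusted p = 2.37e-07, and adjusted p = 0.0509 with an estimated correlation). Of the latter, 11 of 22 were higher and 0 lower (13 and 0 adjusted over the list alone), with a median of 0.66, or 0.21 scaled to total counts (camera adjusted p = 0.000315, and adjusted p = 0.0509 with an estimated correlation). RCA rose by 0.96, RBCS3B by 0.85 and RPL4A by 1.06, and AT3G41768 by 0.65, or 0.22 scaled to total counts. Large rises were those of BT2, a regulator of nitrate and sugar responses, at 2.53, FBA5 at 2.51 and the trehalose-phosphate synthase gene TPS8 at 2.15. The ethylene list had 1 higher and 2 lower of 5 (the same adjusted over the list alone, camera adjusted p = 0.964), a median of 0.06, a mean of -0.15 and a test that pointed downward. EBF1 fell by 0.72, a call lost without ein5-1 ski2-3 replicates 1 and 2 (adjusted p = 0.108). EIL1 fell by 0.83, which was lost without ein5-1 ski2-3 replicate 3 (adjusted p = 0.321), rdr6-11 replicate 2 (0.0758) or triple mutant replicate 1 (0.0871). EBF2 rose by 0.56, which was lost without triple mutant replicate 1 (adjusted p = 0.115) or 2 (0.0541) or ein5-1 ski2-3 replicate 1 (0.0895). No decay gene of 3 was called (camera adjusted p = 0.375).

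Samples separated completely at 57.5% of genes, against 20% by chance for 2 samples and 3. Of the called genes, 34.8% were higher, and 45.5%, 7% and 50.3% with RLE size factors, total counts and MIR scaling. Medians of all genes were -0.21 in the main scaling and -0.09, -0.65 and -0.02 in those alternatives, but 0.02 without ein5-1 ski2-3 replicates 1 and 2, 0.01 without replicate 3, and -0.02 without rdr6-11 replicate 2 or with only the libraries of the groups compared. There were 890 higher and 821 lower genes without ein5-1 ski2-3 replicates 1 and 2, and 1568 and 1234 without replicate 3.

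**Figure D3:**
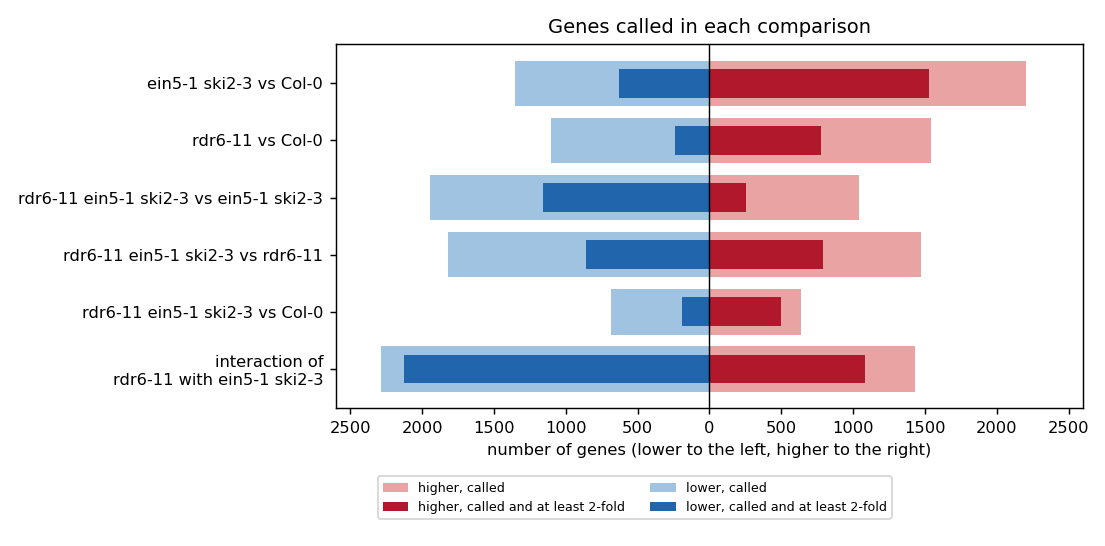
Number of genes called in each of 6 comparisons (horizontal axis, lower genes to the left and higher genes to the right of 0), with light bars for all called genes and dark bars for those that also changed at least 2-fold. The double mutant against Col-0 has 2204 higher genes and the triple mutant against the double mutant 1946 lower genes, while scaled to total counts these numbers are 4498 and 3507.

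RDR6-dependent genes were those at least 2-fold higher in ein5-1 ski2-3 than in Col-0 and at least 2-fold lower in the triple mutant than in ein5-1 ski2-3. There were 763 such RDR6-dependent small RNA genes, of which 658 were protein-coding, 56 untranscribed pseudogenes, 8 MIR genes and 1 a TAS locus, TAS4. The name stands for the rule only. The other TAS loci fell without RDR6 but had not risen 2-fold in ein5-1 ski2-3. Compared with Col-0, 180 of the 763 were still higher in the triple mutant and 20 lower. In rdr6-11, 82 were higher and 32 lower than in Col-0. With 1526 and 1157 genes in the contributing sets, 244.6 shared genes would be met by chance if they were independent. The opposite pattern, lower in ein5-1 ski2-3 and higher in the triple mutant without a fold minimum, held 804 genes against 194.8. An excess over independence is therefore not particular to this set. In 20 simulations with a shared double mutant and no change the overlap was 0, but each called at most 1 gene, so they do not measure the overlap that the shared libraries add to sets of this size. The set held 7 of 8 tested nitrate reductase and SMXL genes, 19 of 24 phased loci and 20 of 27 miRNA targets. None of the 20 photosynthesis, 22 ribosomal protein, 5 ethylene or 2 root genes was in it. Its 658 protein-coding genes held 20.99% to 25.3% of protein-coding counts in ein5-1 ski2-3, and 5.27% to 5.46% in Col-0. In rdr6-11 they held 2.60% to 2.70% and in the triple mutant 3.87% to 4.15%. The rule chose genes higher in ein5-1 ski2-3 than in Col-0 and the triple mutant, so those differences in share are no test of it. In the triple mutant against rdr6-11, which shares the triple mutant libraries by which the set was chosen, 233 of the 763 were higher, 93 lower and 437 not called. As many genes, 763, rose at least 2-fold in the double mutant without meeting the second condition, and 377 of those were higher and 140 lower in that comparison. The set held 2159 genes with libraries scaled to total counts, 373 with DESeq2, 468 with at least 10 counts in at least 3 libraries, and 507 without rRNA, tRNA and organelle genes. Without ein5-1 ski2-3 replicates 1 and 2 it held 417 genes, and without replicate 3 it held 502. The authors' deposited table gives 451 genes at least 2-fold higher in the double mutant than in both other genotypes, of which 444 were in the set. It gives folds over the triple mutant of 13.91 for NIA1, 5.605 for NIA2, 206.2 for SMXL4 and 462.8 for SMXL5.

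**Figure D4:**
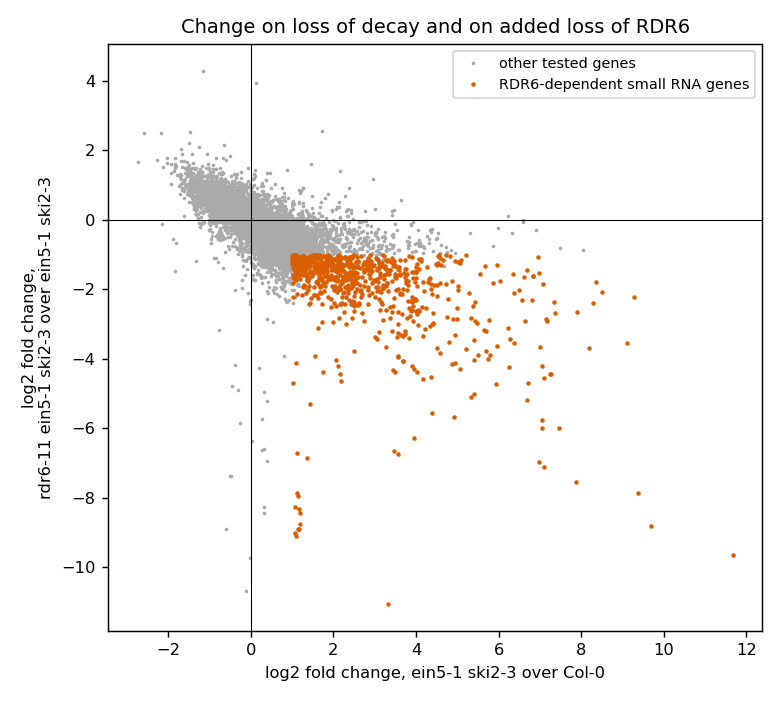
Each point is 1 of 7219 genes, with the fitted log2 fold change of ein5-1 ski2-3 over Col-0 on the horizontal axis and of the triple mutant over ein5-1 ski2-3 on the vertical axis; the 763 RDR6-dependent genes are orange. SMXL5 lies at 9.69 and -8.81, fitted values of genes with 0 counts in a group are not bounds, and part of the downward slope comes from the double mutant libraries that both axes share.

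The comparison of the triple mutant with rdr6-11 asked what losing decay does in the absence of RDR6. Among protein-coding genes 1178 were higher and 301 lower, 931 and 332 scaled to total counts, and 3650 and 8 scaled to MIR genes. Of the 1526 genes at least 2-fold higher in ein5-1 ski2-3 than in Col-0, 610 were among the 1472 higher here. NIA2 rose from 17.6 ± 3.58 CPM (SD, n = 3) to 41.5 ± 4.45 CPM (SD, n = 3), a log2 change of 1.23 (adjusted p = 1.22e-08). EBF1 rose from 10.5 ± 2.08 to 30.3 ± 1.12 CPM. Large rises were those of BBX16, a B-box factor of light responses, with a ratio of 65.0 and a counting interval of 15.3 to 3494, and of the ubiquitin ligase gene PUB25, with a ratio of 46.9 and an interval of 14.8 to 459. MIR genes were lower, as in MIR158a, which went from 1385 ± 17.5 to 449 ± 4.03 CPM, but with libraries scaled to MIR genes it was not called at -0.24. In all, 1472 genes were higher and 1819 lower, of which 791 and 858 changed at least 2-fold.

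The miRNA targets had 13 of 27 higher and 0 lower (the same adjusted over the list alone), with a median of 1.24 (camera adjusted p = 0.00124, and adjusted p = 0.143 with an estimated correlation). REV rose by 3.07, SCL6-IV, a GRAS-family target of miR171, by 1.93, TCP3 by 1.66 and the phosphate homeostasis gene PHO2 by 1.41. Of the nitrate reductase and SMXL genes, 4 of 8 were higher and 0 lower (the same adjusted over the list alone), with a median of 1.00. NIA1 rose by 1.43. SMXL3 rose by 2.72 from 1 count, at a ratio of 6.57 with a counting interval of 1.14 to 378, and the call was lost without ein5-1 ski2-3 replicates 1 and 2 (adjusted p = 0.0701), rdr6-11 replicate 1 (0.109) or 3 (0.116) and triple mutant replicate 1 (0.074) or 2 (0.0764). SMXL7 rose by 1.41 at an adjusted p of 0.0495. Its call was lost without any 1 of 7 libraries or without ein5-1 ski2-3 replicates 1 and 2 together, with the highest adjusted p of 0.345 without triple mutant replicate 1. SMXL4 was not called at 0.76, which was -0.77 without triple mutant replicate 2. The list's camera call (adjusted p = 0.048) was lost with an estimated correlation (adjusted p = 0.28 with an estimated correlation) and without ein5-1 ski2-3 replicates 1 and 2 (adjusted p = 0.0516), rdr6-11 replicate 1 (0.0599) or 3 (0.0637) or triple mutant replicate 2 (0.0558).

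TAS loci regained a little small RNA, with 5 of 8 higher and 0 lower (the same adjusted over the list alone) and a median of 0.87, or 1.23 without TAS3B, which was at or under the floor in both groups. Camera gave an adjusted p of 0.00618, and adjusted p = 0.251 with an estimated correlation. TAS3A rose from 6.75 ± 0.885 to 23.7 ± 5.69 CPM, TAS1B by 1.44, TAS1C by 1.28 and TAS2 by 1.23. TAS1A rose by 0.52, a call lost without rdr6-11 replicate 2 (adjusted p = 0.0752) or 3 (0.0624) or triple mutant replicate 2 (0.0530). TAS3C and TAS4 were not called at -0.67 and -0.73, which became 0.63 and 0.38 scaled to MIR genes. The phased loci did not move as a list (3 higher and 3 lower of 24, 3 and 2 adjusted over the list alone, camera adjusted p = 0.96). Their median was 0.04 (-0.04 scaled to total counts), their mean 0.18, and the test pointed downward. AFB2 rose by 1.40 and the PPR pseudogene AT1G62860 fell by 1.56, which was -0.17 without a call when scaled to MIR genes.

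Of 108 MIR genes, 98 were lower and 1 higher (99 and 2 adjusted over the list alone), with a median of -1.22 that was 0.16 scaled to MIR genes (camera adjusted p = 2.87e-70, and adjusted p = 0.0195 with an estimated correlation). MIR166f and MIR159b fell by 1.56 and 1.39, and stood at -0.18 and 0 scaled to MIR genes. Untranscribed pseudogenes fell at 1313 of 1852 and rose at 5, with a median of -0.83, but 0 fell and 796 rose with a median of 0.56 scaled to MIR genes. PSEUDOSRKA fell by 4.64 and kept 3 counts, with a counting interval of 9.11- to 136-fold. Transposon genes had 4 higher and 7 lower of 15 (the same adjusted over the list alone), with a median of -0.56 that was 0.82 scaled to MIR genes (camera adjusted p = 2.80e-05, and adjusted p = 0.0278 with an estimated correlation). The call rested on AT3G44570, AT2G14000 and AT3G30820: without them 4 were higher and 4 lower of 12, the median was 0.56 and the test pointed upward (camera adjusted p = 0.54). AT3G44570 fell from 203 ± 4.68 to 0.626 ± 0.571 CPM, AT2G14000 by 5.66 and AT3G30820 by 5.07. The adjacent gene AT3G44580 kept 3 counts, and its drop had a counting interval of 121- to 1716-fold. ADC1 rose by 1.68.

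Photosynthesis genes were higher at 19 of 20 and lower at 0 (20 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 1.14e-06, and adjusted p = 0.0815 with an estimated correlation). LHCB1.2, a light-harvesting antenna gene, rose by 0.59 and RCA by 0.56. Ribosomal protein genes were higher at 8 of 22 and lower at 0 (7 and 0 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 0.0207, and adjusted p = 0.136 with an estimated correlation). RPL27AC rose by 0.76 and AT3G41768 by 0.26. Scaled to total counts, the 4 nuclear rRNA genes had a median of -0.02, with 2 higher and 2 lower. The ethylene list had 2 higher and 0 lower of 5 (the same adjusted over the list alone), with EBF1 up by 1.53 and EBF2 by 0.83. Its call (camera adjusted p = 0.0441) was lost with an estimated correlation (adjusted p = 0.136 with an estimated correlation) and without ein5-1 ski2-3 replicates 1 and 2 (adjusted p = 0.0516), rdr6-11 replicate 2 (0.0915) or 3 (0.0637) or triple mutant replicate 2 (0.0558). Of the decay list, 2 of 3 were higher and 0 lower (the same adjusted over the list alone, camera adjusted p = 0.273). RH6, a helicase gene of P-bodies, rose by 1.28, a call lost without triple mutant replicate 2 (adjusted p = 0.0807). VCS, a decapping scaffold gene, rose by 0.79, lost without rdr6-11 replicate 1 (adjusted p = 0.0608) or 3 (0.23) or triple mutant replicate 2 (0.116) or 3 (0.0816). The root gene SHR rose by 2.09.

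Samples separated completely at 54.2% of genes, against 10% by chance. Of the called genes, 44.7% were higher, and 44.6%, 37.5% and 99.7% with RLE size factors, total counts and MIR scaling. Medians of all genes were 0.12 in the main scaling and 0.12, 0.03 and 1.50 in those alternatives.

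The comparison of the triple mutant with Col-0 asked what losing RDR6 and decay together does. The triple mutant had almost no TAS small RNA, and 516 protein-coding genes had more small RNA than in Col-0. All 8 TAS loci were lower. TAS2 fell by 6.34 (adjusted p = 4.95e-41), TAS1A by 6.11, TAS1C by 5.21, TAS1B by 4.07, TAS3A by 3.93 and TAS3C by 3.12. TAS3B was at least 80.3-fold lower, and TAS4 kept 1 count, with a counting interval of 50.6- to 11300-fold. The PPR genes AT1G63630 and RPF1, both with 0 counts in the triple mutant, were at least 197-fold and at least 94.9-fold lower, and SPL2 fell by 4.63. Genes that rose included NIA2, from 21.2 ± 1.23 to 41.5 ± 4.45 CPM (SD, n = 3 in each group), NIA1 by 1.91, EBF1 by 1.25, SCL6-IV by 1.85 and MIR845a by 3.97. CRF6, a cytokinin response factor gene with 0 counts in Col-0, was at least 11.8-fold higher, and SHR had a ratio of 11.2 with a counting interval of 3.17 to 107. GRP7, a clock-controlled RNA-binding protein gene, rose by 0.42, and MIR158a fell by 1.02. AT3G44570 fell by 7.84. The 18S rRNA gene AT3G41768 fell by 0.38, which was 0.24 scaled to MIR genes. In all, 635 genes were higher and 687 lower, of which 497 and 191 changed at least 2-fold, and 142 of the lower genes were protein-coding. The protein-coding split was 1048 higher to 61 lower scaled to total counts, and 1571 to 47 scaled to MIR genes. Complete separation was seen at 32.8% of genes, against 10% by chance. Of the called genes, 48% were higher, and 47%, 86.7% and 95.4% with RLE size factors, total counts and MIR scaling, where medians of all genes were 0.02, 0.41 and 0.65 against 0.03 in the main scaling.

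The interaction asked whether losing RDR6 changes small RNA differently in ein5-1 ski2-3 than in wild type. Nitrate reductase and SMXL genes, MIR genes and transposon genes had lower values by camera, meaning a larger drop or smaller rise in the decay mutant, while photosynthesis and ribosomal protein genes had higher values. No list kept its call with an estimated correlation, where the lowest value was adjusted p = 0.0606 with an estimated correlation. Fry compares a list with no change rather than with the other genes, and was run in the main scaling only. It called each list named above and the TAS loci (fry adjusted p from 7.91e-06 to 0.0055). It also called miRNA targets (0.00251), decay genes (0.00767) and phased loci (0.0391), which camera did not. The MIR median was 0.01 scaled to MIR genes, which draws it towards 0 by construction. The transposon call was lost without 3 loci near 0 in the triple mutant. The interaction was -9.51 for SMXL5 (adjusted p = 1.74e-14), -4.27 for NIA1 and -2.22 for NIA2 on the log2 scale. The miRNA targets ARF6 and PHB had -5.23 and -4.03. Of the TAS loci, 5 had positive values, meaning a smaller drop in the decay mutant: 2.56 for TAS3A, 1.58 for TAS1C, 1.24 for TAS1B, 1.21 for TAS2 and 0.78 for TAS1A, although TAS1A stood at -0.13 scaled to total counts. TAS4 had -4.06, from 2 counts in rdr6-11 and 1 in the triple mutant. Its call (adjusted p = 0.043) was lost without ein5-1 ski2-3 replicates 1 and 2 (0.084) or 3 (0.0516), rdr6-11 replicate 2 (0.165) or 3 (0.178) or triple mutant replicate 1 (0.0698) or 3 (0.0776), and also with libraries scaled to MIR genes. TAS3C and TAS3B were not called at -1.47 and -1.34, and TAS3B stood at 0.8 without rdr6-11 replicate 2. In all, 1431 genes were higher and 2286 lower, of which 1082 and 2125 by at least 2-fold, and protein-coding genes made up 821 and 671. That split turned to 106 and 1337 scaled to total counts, and was 1795 and 166 scaled to MIR genes.

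Of the nitrate reductase and SMXL genes, 6 of 8 were lower and 0 higher (the same adjusted over the list alone), with a median of -3.51 (camera adjusted p = 0.00527, and adjusted p = 0.184 with an estimated correlation). TAS loci had 5 higher and 1 lower of 8 (the same adjusted over the list alone), with a median of 1.00 and a mean of 0.06, and 2 higher and 2 lower with a median of 0.08 scaled to total counts (camera adjusted p = 0.00918, and adjusted p = 0.327 with an estimated correlation). Phased loci had 13 lower and 0 higher of 24 (14 and 0 adjusted over the list alone) and did not pass camera (adjusted p = 0.0743), except without ein5-1 ski2-3 replicate 3 (0.029). The miRNA targets had 14 lower and 1 higher of 27 (15 and 1 adjusted over the list alone) and did not pass either (adjusted p = 0.0594). Their list passed without Col-0 replicate 2 (0.0343), ein5-1 ski2-3 replicate 1 (0.0490), 2 (0.0436), 1 and 2 together (0.0314) or 3 (0.04), rdr6-11 replicate 2 (0.0370) or triple mutant replicate 3 (0.0317). MIR genes had 78 lower and 4 higher of 108 (82 and 4 adjusted over the list alone), with a median of -0.93 that was 0.01 scaled to MIR genes (camera adjusted p = 8.91e-15, and adjusted p = 0.184 with an estimated correlation). MIR408 had -2.82, MIR398b -1.66 and MIR166a -0.95. Transposon genes had 8 lower and 1 higher of 15 (the same adjusted over the list alone), with a median of -1.81 that was -0.62 without ein5-1 ski2-3 replicate 3 and -0.86 scaled to MIR genes (camera adjusted p = 0.000339, and adjusted p = 0.085 with an estimated correlation). AT3G44570 had -7.77, and without it, AT2G14000 and AT3G30820 the list had a median of -0.65 and a camera adjusted p of 0.528.

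Photosynthesis genes had 18 higher and 0 lower of 20 (the same adjusted over the list alone), with a median of 1.28, or 0.36 scaled to total counts (camera adjusted p = 2.12e-13, and adjusted p = 0.0606 with an estimated correlation), RCA at 1.63 and RBCS3B at 1.47, or 0.72 and 0.57 scaled to total counts. Ribosomal protein genes had 13 higher and 0 lower of 22 (17 and 0 adjusted over the list alone), with a median of 1.11, or 0.19 scaled to total counts (camera adjusted p = 0.000654, and adjusted p = 0.0873 with an estimated correlation) and RPL27AC at 1.65, which was not called at 0.73 scaled to total counts. AT3G41768 had 1.3, or 0.39 scaled to total counts. The ethylene list had 1 higher and 0 lower of 5 (the same adjusted over the list alone, camera adjusted p = 0.818), with a median of 0.01, a mean of -0.02 and a test that pointed upward. No decay gene of 3 was called (camera adjusted p = 0.528). Of the called genes, 38.5% had a positive value, and 44.6%, 8.6% and 85.8% with RLE size factors, total counts and MIR scaling. Medians of all genes were -0.31 in the main scaling and -0.18, -1.22 and 0.61 in those alternatives, and -0.12 and -0.08 without ein5-1 ski2-3 replicates 1 and 2 or replicate 3. Without replicate 3 there were 1921 higher and 1945 lower genes.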

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

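The tests of MIR genes and pseudogenes, the depth ratio, the summed counts of neighbouring genes and the count-ratio test of the retrotransposon loci were chosen only after the result was seen, while the other splits of the libraries, the shared-sequence test and the test of falls among neighbouring genes were set before. A difference between the effect of rdr6-11 in ein5-1 ski2-3 and its effect in wild type, tested as an interaction at adjusted p < 0.05, flagged each result in the next paragraph.

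No list below kept its call with an estimated correlation. The nitrate reductase and SMXL list (adjusted p = 0.184 with an estimated correlation) had a median interaction of -3.51, with SMXL5 at -9.51, NIA1 at -4.27 and NIA2 at -2.22. The miRNA targets ARF6 and PHB had -5.23 and -4.03. TAS loci (adjusted p = 0.327 with an estimated correlation) had a median of 1.00, which was 0.08 scaled to total counts, with TAS3A at 2.56, TAS1C at 1.58, TAS1B at 1.24, TAS2 at 1.21, TAS1A at 0.78 and TAS4 at -4.06, while TAS3C at -1.47 and TAS3B at -1.34 were not called. Photosynthesis genes (adjusted p = 0.0606 with an estimated correlation) had a median of 1.28, or 0.36 scaled to total counts, with RCA at 1.63 and RBCS3B at 1.47, and ribosomal protein genes (adjusted p = 0.0873 with an estimated correlation) one of 1.11, or 0.19 scaled to total counts, with RPL27AC at 1.65. MIR genes (adjusted p = 0.184 with an estimated correlation) had a median of -0.93, which was 0.01 scaled to MIR genes, with MIR408 at -2.82, MIR398b at -1.66 and MIR166a at -0.95. Transposon genes (adjusted p = 0.085 with an estimated correlation) had a median of -1.81, with AT3G44570 at -7.77, but -0.62 without ein5-1 ski2-3 replicate 3, -0.86 scaled to MIR genes, and -0.65 without the call when AT3G44570, AT2G14000 and AT3G30820 were left out. The 18S rRNA gene AT3G41768 had 1.3, or 0.39 scaled to total counts.

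MIR genes and untranscribed pseudogenes rose together in rdr6-11 and fell together in the triple mutant against rdr6-11. The loss of RDR6 as the sole cause is argued against by the triple mutant against ein5-1 ski2-3, where MIR genes had a median of -0.1. Their median in rdr6-11 against Col-0 was 0.76. The value of -0.1 was 0.02 with RLE size factors and -0.55 scaled to total counts, and turned positive without ein5-1 ski2-3 replicates 1 and 2. MIR genes held a larger share of the rdr6-11 libraries, 5.29% to 6.09% against 2.29% to 2.45% in Col-0. Whether a shift towards microRNA-type small RNA also lies behind the pseudogene rise in rdr6-11 stays open. Pseudogenes had a median of 0.16 in rdr6-11 with libraries scaled to MIR genes, but that restates that both classes rose alike. The same shift is argued against for the pseudogene rise in ein5-1 ski2-3, which stood at 1.04 in that scaling. A shift between libraries without a genotype could add to the pattern, because both classes had lower shares in ein5-1 ski2-3 replicate 3 than in replicates 1 and 2, with medians of -0.47 and -0.32.

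The retrotransposon loci AT3G44570, AT2G14000 and AT3G30820 and the adjacent AT3G44580 had 0 to 7 counts in each triple mutant library. Lower depth is argued against, since the triple mutant libraries had 1.008 times the mean total count of the others, and so is a lost stretch that takes in the genes within 50 kb, whose summed counts had a lower 95% bound of 0.49 times those of ein5-1 ski2-3 and higher bounds against the other genotypes. Reads of 1 source locus counted at every copy stay open, because shared words do not bound shared reads. Of the 24-base words of AT2G14000 or AT3G30820, at most 4.8% were found in AT3G44570 or AT3G44580. Those adjacent loci shared 173 words with each other, 12.3% of AT3G44570 and 11.7% of AT3G44580, all on opposite strands. The 4 loci also kept one count ratio over the other 9 libraries (chi-square 11.52 on 24 degrees of freedom). A shorter lost stretch at AT3G44570 and AT3G44580 stays open for those loci, because only 1 gene within 50 kb was tested, and 0 fell at least 4-fold against each other genotype.

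The 4 genotypes were also split in other ways. Of 10 splits in each comparison of 2 genotypes, 1 gave as many calls, the real one, and 10 splits are too few for a share under 0.05. The real split gave 3560 calls in ein5-1 ski2-3 against Col-0 and the highest other 447. These numbers were 2645 and 0 in rdr6-11 against Col-0, and 2983 and 115 in the triple mutant against ein5-1 ski2-3. They were 3291 and 0 against rdr6-11, and 1322 and 0 against Col-0. For the interaction, 1 of 100 splits gave as many calls (3717, with 2925 as the highest other). For the RDR6-dependent genes, 1 of 100 did (763, with 666 as the highest other). Both sets of splits shuffled all samples over the 4 genotypes, so they argue only against there being no difference between any genotypes. They cannot test the interaction or the RDR6 dependence apart from other differences between the genotypes.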

How the results depend on the processing

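The 12 libraries counted apart were the fit first planned, before ein5-1 ski2-3 replicates 1 and 2 were summed. Alternatives chosen after seeing the data were the replicate block with the libraries apart, the fits without rRNA, tRNA and organelle genes, the RDR6-dependent set from only the groups compared, and the transposon list without AT3G44570, AT2G14000 and AT3G30820. Alternatives for normalized values, a pseudocount and a mean filter, do not apply to counts and were not run. Each result was tallied once under each alternative. Counts of calls stayed within 1.5 times the main count in 365 such pairs of result and alternative, and moved further in 55. Named genes kept direction and side of the threshold in 4342 pairs, were weaker in 141, stronger in 11 and turned in 28. Lists were the same in 980, weaker in 39, stronger in 29 and turned in 27. In some pairs the left-out library belonged to no group of the contrast, so the tallies do not measure robustness. Where ein5-1 ski2-3 kept 1 sample, it was assumed to vary like the other groups. Depth limits the folds of genes with few counts, such as SMXL3 with 1 count in rdr6-11, but was not varied. A fold minimum can only lower a count. For the other changes below, the cause was not tested.

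With libraries scaled to total counts, ein5-1 ski2-3 had 4498 higher and 234 lower genes than Col-0, rdr6-11 had 2371 and 431, and the triple mutant 1591 and 245. The triple mutant had 265 higher and 3507 lower genes than ein5-1 ski2-3, the interaction 324 and 3453, and there were 2159 RDR6-dependent small RNA genes. Scaled to MIR genes, ein5-1 ski2-3 had 544 lower genes, rdr6-11 had 50 higher and 2799 lower, and the triple mutant 2517 and 120, each against Col-0. The triple mutant had 1047 lower genes than ein5-1 ski2-3 and 5418 higher and 16 lower than rdr6-11, and the interaction had 2624 and 433. DESeq2 gave 1232 higher genes in ein5-1 ski2-3 and 355 in the triple mutant against Col-0, and 756 lower genes in the triple mutant against ein5-1 ski2-3. It gave 877 higher and 1181 lower against rdr6-11, 1413 lower in the interaction and 373 RDR6-dependent genes.

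Without a filter, rdr6-11 had 730 lower genes than Col-0 and the triple mutant 928 higher than rdr6-11. With at least 10 counts in at least 3 libraries, there were 468 RDR6-dependent small RNA genes, and without a fold minimum 1421. With a 2-fold minimum, 629 genes were lower in ein5-1 ski2-3, 776 higher and 238 lower in rdr6-11, and 191 lower in the triple mutant, each against Col-0. It left 257 higher and 1157 lower genes in the triple mutant against ein5-1 ski2-3, and 791 and 858 against rdr6-11. Without rRNA, tRNA and organelle genes, 1448 genes were higher in ein5-1 ski2-3 and 349 lower in the triple mutant against Col-0, and 507 were RDR6-dependent. With the replicate block (libraries paired by number, 12 counted apart), ein5-1 ski2-3 had 2161 higher and 1393 lower genes than Col-0, against 2169 and 1397 without it, and 736 genes were RDR6-dependent. The share of counts from genes higher in ein5-1 ski2-3 was 7.264%, and 37.03% of protein-coding counts.

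Leaving out 1 library at a time, or ein5-1 ski2-3 replicates 1 and 2, gave 1220 to 2224 higher and 1189 to 1839 lower genes in ein5-1 ski2-3 against Col-0. In rdr6-11 it gave 1239 to 1623 and 882 to 1137. The triple mutant had 830 to 1568 higher and 821 to 1956 lower genes than ein5-1 ski2-3, 1097 to 1508 and 1482 to 1987 than rdr6-11, and 479 to 639 and 613 to 731 than Col-0. The interaction had 1288 to 1921 and 1585 to 2195, and the RDR6-dependent small RNA genes numbered 417 to 767. The share of counts from genes higher in ein5-1 ski2-3 was 6.449% to 8.079%.

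With an estimated correlation, camera called 1 list in ein5-1 ski2-3 and 2 in rdr6-11 against Col-0, 4 and 2 in the triple mutant against ein5-1 ski2-3 and rdr6-11, and 0 in the interaction; fry called 7 in rdr6-11. Without AT3G44570, AT2G14000 and AT3G30820, transposon genes lost their calls, and turned in the triple mutant against rdr6-11 (0.56). The other list tests that turned were not called on either side, and their medians follow. In ein5-1 ski2-3 against Col-0, TAS loci turned without a filter (-0.03), without rRNA, tRNA and organelle genes (-0.3), and in left-out libraries (-0.55 to -0.32). Decay genes turned with fry (0.08) and in left-out libraries (0.1 to 0.18), and transposon genes without rRNA, tRNA and organelle genes (-0.41). In rdr6-11, the nitrate reductase and SMXL list (-0.93) and decay genes (-0.95) turned scaled to MIR genes. In the triple mutant against ein5-1 ski2-3, ethylene genes turned scaled to MIR genes (0.22), without rRNA, tRNA and organelle genes (0.12) and in 7 fits without a library (range over all such fits -0.08 to 0.43), and MIR genes without ein5-1 ski2-3 replicates 1 and 2 (0.19). Against rdr6-11, phased loci turned scaled to total counts (-0.04), with 12 libraries apart (0.03), with the replicate block (0.04), without rRNA, tRNA and organelle genes (0.09) and without rdr6-11 replicate 2 (0.12) or triple mutant replicate 1 (0.18), in a range of -0.01 to 0.18.

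Of named genes in ein5-1 ski2-3 against Col-0, these turned scaled to total counts: TAS1A (0.56), TAS1C (0.53), TAS3A (0.07), TAS3B (0.23) and AT3G44570 (0.36). Scaled to MIR genes, TAS1A (0.2) and TAS1C (0.16) turned. TAS1B turned with only the compared groups (-0.04) and without ein5-1 ski2-3 replicates 1 and 2 (-0.26). TAS2 turned with RLE size factors and DESeq2 (-0.11 each), with only the compared groups (-0.22), without rRNA, tRNA and organelle genes (-0.16) and in left-out libraries (-0.41, -0.17 and -0.03). In rdr6-11 against Col-0, NIA2 (0.21) and EBF1 (0.18) turned scaled to total counts, and MIR159b (-0.17) and AT3G44570 (-0.37) scaled to MIR genes. In the triple mutant against rdr6-11, TAS3C (0.63), TAS4 (0.38) and MIR159b (0) turned scaled to MIR genes, TAS3B without rdr6-11 replicate 2 (0, in a range of -2.4 to 0) and SMXL4 without triple mutant replicate 2 (-0.77, in a range of -0.77 to 1.57). AT3G41768 turned against Col-0 scaled to MIR genes (0.24), the interaction of TAS1A scaled to total counts (-0.13) and that of TAS3B without rdr6-11 replicate 2 (0.8, in a range of -1.81 to 0.8).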

Other observations

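The tests of exon number among all risers and of miRNA targets were chosen only after the result was seen, and that of exon number within the RDR6-dependent genes was set before. The genes of the next paragraph were chosen after their values were seen.

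RDR6-dependent genes outside the lists included BRI1, the brassinosteroid receptor gene, with a log2 change of 5.07 in ein5-1 ski2-3 over Col-0 and of -4.30 in the triple mutant over ein5-1 ski2-3. PXY, a receptor kinase gene of vascular stem cells, had 4.88 and -4.16. LOX4, a lipoxygenase gene of jasmonate synthesis, had 5.65 and -3.18 with 4 counts in Col-0, and JAZ1, a jasmonate repressor gene, 4.41 and -2.69 with 6 counts.

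Of the 27 tested miRNA targets, 20 were RDR6-dependent, against 638 of 4172 other protein-coding genes (15.3%, 2-sided Fisher's exact p = 1.84e-11). Among genes at least 2-fold higher in ein5-1 ski2-3, 20 of 23 targets were RDR6-dependent, against 638 of 1147 others (55.6%, exact p = 0.00238). These values go the way of the hypothesis that RDR6 takes miRNA-cleaved transcripts more often, found and tested on the same data. They do not decide it. The comparison with all other genes partly restates that most tested targets rose. The comparison among risers did not match the genes on level or on size of the rise, and a larger rise leaves more room for a 2-fold fall.

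Genes with 1 exon made up 33.4% of the RDR6-dependent genes (220 of 658) and 37.5% of the other risers (192 of 512). Their odds ratio was 0.84 with a 95% interval of 0.65 to 1.07 (2-sided Fisher's exact p = 0.156). The higher share predicted if RDR6 takes such genes more often was therefore not seen. The sets were not matched on level or on size of the rise, so this does not decide the question. Both sets of risers together had more of them than the other tested protein-coding genes, of which 281 of 3029 (9.3%) had 1 exon, with an odds ratio of 5.31 and a 95% interval of 4.46 to 6.34. Within 5 bins of level the Mantel-Haenszel odds ratio was 4.75, with a lower bound of 3.91. In each bin more risers had 1 exon, 25.7% to 40.1% against 7.7% to 11.8% of the other genes. Bin 1 held 553 risers and 287 other genes, and bin 5 held 117 and 723. A gene near 0 elsewhere can pass the filter through ein5-1 ski2-3 alone, so these bins may not separate level from the rise. A difference in level as the whole cause therefore stays open. The hypothesis that transcripts without introns give small RNA more often when decay is lost stays open as well. The odds ratio of 4.75 restates what prompted it, and transcript length was not tested.

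AT1G63630, AT4G17587 and AT4G22485 were, with the 3 retrotransposon loci and the adjacent AT3G44580, the 7 genes whose fitted values were at least 4-fold lower in the triple mutant than in each other genotype. For AT1G63630, with 8 counts in rdr6-11 and 0 in the triple mutant, the counts do not bound the fold against rdr6-11 at 4. Nor do the counts of AT4G17587 and AT4G22485 against Col-0, where the ranges overlap. AT4G17587 had 1 to 7 counts per Col-0 library and 0 to 2 per triple mutant library. AT4G22485 had 5 to 21 and 0 to 7. AT1G50040 was the 1 gene at least 4-fold higher than in each, with 4.05 ± 0.984 CPM (SD, n = 3), and these genes were chosen after their values were seen.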
